A study of Homo sapiens with 121 samples.

How the data were processed

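Single cells of the MDA-MB-231 line with luciferase were sorted into plates, and each deposited sample is 1 cell. Libraries were made with a modified Smart-seq2 protocol, per the labels. The amount of spike-in RNA added is not given in the sources used here, but the table has rows for it and every cell holds reads of it. The deposited table holds whole-number read counts per gene and cell, with no normalization. STAR, HTSeq and the hg19 build are named in the submitters' processing notes, while tool versions, the annotation and the strand setting are not given in the sources used here. Cells were assigned to the groups PKH26 high (46 cells), PKH26 low (45) and G1 adherent (30) from their labels, and each of the 121 columns of the table matched the label of a single sample. The table lists 59746 genes and 92 spike-in rows. Gene IDs were matched without their version to GENCODE 44 on GRCh37 coordinates, which share the hg19 build, and 54545 IDs received a symbol. IDs without a symbol held at most 0.440% of a cell's gene reads. Coordinates are those of that annotation, counted from 1.

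Spike-in reads, between 0.0161% and 0.534% of a cell's reads, were left out of all totals. A cell was kept with at least 50000 reads over genes and 1000 genes with a read, and all 121 cells passed. No pair of cells held identical counts, and the highest correlation of log values between 2 cells across genes was 0.736. The counts of each group were summed and expressed as CPM, the counts scaled to the summed gene reads. Genes with at least 5 CPM in a group were kept for list medians, which left 10883. Folds between groups are on the log2(CPM + 1) scale, which understates the difference of low genes. Where a group had no read of a gene, the fold is given against a floor of 3 reads over the group. The lower 95% counting limits of such folds are smaller than the folds given. Intervals of CPM are exact Poisson 95% intervals and intervals of shares of cells are exact binomial (Clopper-Pearson) 95% intervals. Intervals and floors cover counting error only, and PCR copies were counted as reads because the libraries carry no molecular identifiers, so they understate the uncertainty between cells and between cultures.

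The labels name no separate cultures, so each group was treated as 1 sample. Cells are not replicates, and no p-value, standard error or number of changed genes was computed. PKH26 high and low cells share plates 2 and 4, and their folds were also computed within each plate. G1 adherent cells lie on plates A (26 cells) and B (4 cells) and were handled on another date. They were also stained with another dye and sorted by another gate. Plate, date, staining, gate and culture therefore cannot be told apart. Shares of cells with a read and numbers of genes per cell were taken after thinning each cell to 500000 reads, which 45 PKH26 high, 43 PKH26 low and 30 G1 adherent cells reached and 3 cells did not. Without thinning, the median numbers of genes per cell were 5777, 5549 and 5663. Principal components were computed from log2(CPM + 1) of the 1000 most variable genes in the thinned cells.

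The groups, comparisons, filters, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The 29 gene lists held 689 entries, of which 8 (UHRF1, HN1, TXNIP, CD24, ACACA, CCL5, SOD2 and PECAM1) matched no symbol used here and were not analysed. For each of the 26 lists with at least 5 members past the filter, the median log2 fold was given with a binomial order-statistic 95% interval over its members and with its percentile among 10000 random lists of the same size drawn from 20 bins of mean expression. This percentile describes these libraries and is not a test. The remaining 3 lists held markers of leukocytes, endothelial cells and erythroid cells as controls.

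For PKH26 high against low, the rule named the 12 genes with the highest and the 12 with the lowest log2 fold among genes with at least 20 CPM and a read in at least 25% of thinned cells in the higher group, and an absolute log2 fold of at least 1 in the same direction in the sums, in plate 2, in plate 4 and with equal weight per cell. For mammosphere against adherent cells it ranked genes by the smaller of the folds of both PKH26 groups against G1 adherent cells, under the same limits. Symbols of clone, antisense or pseudogene form were left out of these rankings. From each list, up to 4 members with the largest absolute fold among those with at least 20 CPM were named, though the folds of 2 genes are not reported here, and MKI67, TOP2A, CCNB1, CDKN1A, CDKN1B, CD44, ALDH1A3, PROM1 and VIM were always reported. GCG, MALAT1, NEAT1, MT-RNR2, CXCL8, further members of the lists and the genes that lead a component were chosen after their values were seen. Genes with close copies elsewhere in the genome, such as ribosomal protein, ferritin, keratin, heat shock and mitochondrially encoded genes, may lose or gain reads in counting, and their levels are uncertain. The protocol does not mark the strand, so reads of a gene and of an overlapping antisense gene, as at MT-ND6, cannot be told apart.

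The steps were tested on simulated cells drawn from the means, depths and spread of the PKH26 cells, and for mammosphere against adherent cells from those of all cells, with 9841 genes each. Of genes simulated with 2-fold, 4-fold and 8-fold differences between PKH26 high and low cells, the median recovered log2 fold was 0.97, 2.02 and 3.05, the sign was right in 100% and the naming rule was met by 26.9%, 83.3% and 97.0%. Of 9641 genes simulated with no difference, 241 (2.50%) met the rule by chance. On the lower side about as many measured genes met it as simulated ones without a difference, so meeting the rule does not by itself show a difference. Of 200 simulated lists of 50 unchanged genes, 8 fell outside the central 95% of random lists, and each of 20 lists with 20 members lowered 2-fold fell at or below the lower limit. The simulated genes vary independently from cell to cell. These counts therefore do not show how often lists of genes that vary together fall outside. Alternatives were equal weight per cell, thinned cells, TMM factors and median-of-ratios size factors, totals without mitochondrially encoded and ribosomal protein genes, other cell and gene filters, pseudocounts of 0.1 and 5 CPM, leaving out the deepest cell of each group, single plates and other thinning depths. Leaving out cells above 15% mitochondrial reads was added after the data were seen. Python 3.11.15 was used with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, the last 2 only for scaling factors.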

Results

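Reads per gene were counted in single cells of MDA-MB-231, an established breast cancer line with a mesenchymal phenotype, in a derivative that carries luciferase. The cells were sorted by flow cytometry into the wells of plates and their RNA was converted to full-length cDNA with a modified Smart-seq2 protocol, which uses no molecular identifiers. Of these cells, 91 came from non-adherent cultures in which they grew as mammospheres for 120 h after staining with 1 µM PKH26, a membrane dye that is shared out between daughter cells at each division. The labels describe the 46 cells that kept much dye (PKH26 high) as low in proliferation and the 45 cells that had lost most of it (PKH26 low) as high in proliferation. PKH26 high and low cells shared plates 2 and 4. The remaining 30 cells came from adherent culture and were sorted as G1 cells by low DNA content after staining with 5 µM of the DNA dye DyeCycle Violet. They lay on 2 other plates and were handled on another date. The cells held between 126630 and 2241211 reads over genes, with medians of 1242930 in PKH26 high, 1420360 in PKH26 low and 1397500 in G1 adherent cells. The summed reads of these groups were 62194038, 61587434 and 41731561. At an equal depth of 500000 reads, a median of 5214 genes was read in PKH26 high cells (range 3589 to 6620), 5239 in PKH26 low cells (3663 to 6522) and 5257.5 in G1 adherent cells (3162 to 7685). Each group counted as 1 sample, because the labels name no separate cultures, so no difference had a replicate check and no test was made.

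The comparison of PKH26 high with PKH26 low cells asks how cells that divided little in mammosphere culture differ from cells that divided often. Genes of G2 and mitosis were lower in PKH26 high cells. The median log2 fold of the 52 measured members of the G2/M list was -0.69 (95% interval over members -0.96 to -0.50), and 46 members were lower, 36 of them in both plates. CCNB1, the cyclin that drives entry into mitosis (ENSG00000134057.10, chromosome 5, 68462962 to 68474072), stood at 150.2 CPM in PKH26 high cells (95% Poisson interval 147 to 153) and at 856 CPM in PKH26 low cells (848.5 to 863), a log2 fold of -2.50. PLK1, a kinase of the mitotic spindle (ENSG00000166851.10, chromosome 16, 23688977 to 23701688), stood at 27.3 CPM (26.0 to 28.6) and 193 CPM (190 to 196), a log2 fold of -2.78. GAS2L3, a linker of microtubules and actin used in cell division (ENSG00000139354.6, chromosome 12, 100967461 to 101022066), stood at 0.868 CPM (0.652 to 1.13) and 25.1 CPM (23.9 to 26.4), a log2 fold of -3.81. HJURP, the chaperone that loads the centromeric histone CENPA, had a log2 fold of -1.92, and CDC20, an activator of the anaphase-promoting complex, one of -1.83. The summed G2/M list took 5211 CPM in PKH26 high cells and 9139 CPM in PKH26 low cells.

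The G2/M difference held within each plate, with a list median of -0.70 in plate 2 and -0.73 in plate 4, and the median lay at percentile 0 among 10000 random lists matched on expression. At equal depth, reads of CCNB1 were found in 22 of 45 PKH26 high cells (48.9%, exact binomial 95% interval 33.7 to 64.2) and in 29 of 43 PKH26 low cells (67.4%, 51.5 to 80.9), and the intervals of these shares overlapped. A PKH26 high cell held reads of a median of 14 genes of the list (range 6 to 49) and a PKH26 low cell of 22 (4 to 51). Within plates these medians were 15 and 28.5 in plate 2, and 13 and 15 in plate 4. Between the plates, the same group differed in the list by 0.44 on the log2 scale for PKH26 high cells and 0.40 for PKH26 low cells, plate 2 over plate 4.

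**Figure D1:**
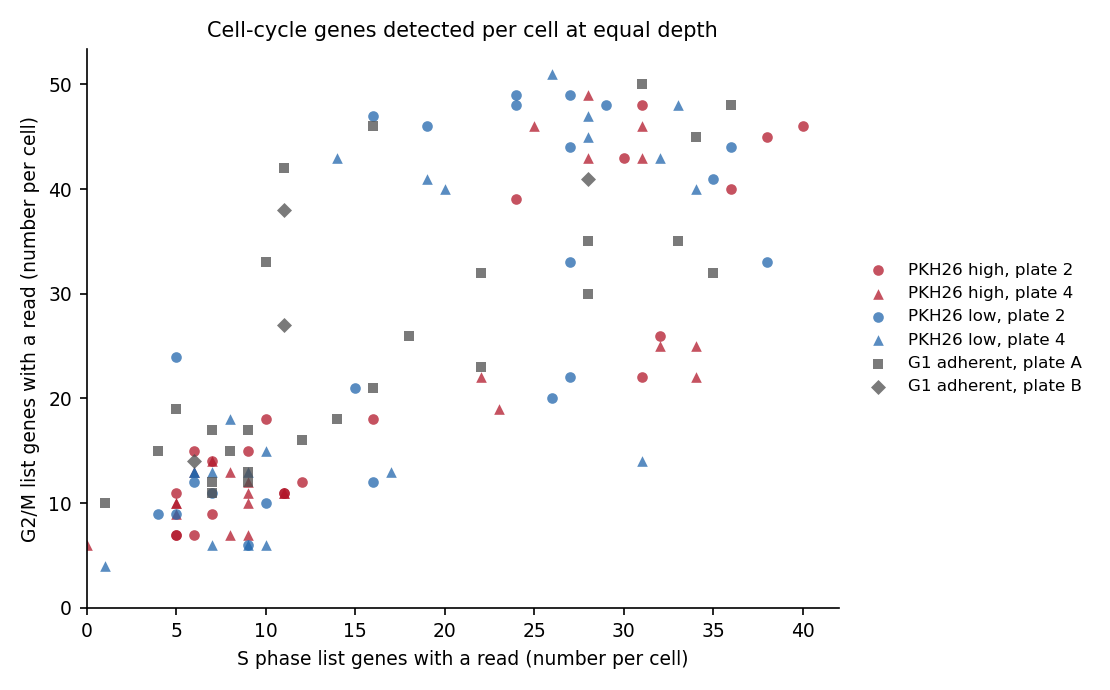
Number of S phase list genes (horizontal axis) and of G2/M list genes (vertical axis) with a read in each cell thinned to 500000 reads, with 1 point per cell, colours for the 3 groups and mark shapes for the plates. The G2/M medians are 14 genes in PKH26 high, 22 in PKH26 low and 24.5 in G1 adherent cells, and each group holds cells low on both axes as well as cells with more than 40 G2/M genes.

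MKI67, the gene of the proliferation antigen Ki-67 (ENSG00000148773.8, chromosome 10, 129894923 to 129924687), stood at 152 CPM (149 to 155.4) in PKH26 high and 164.9 CPM (162 to 168) in PKH26 low cells. Its log2 fold was 0.61 in plate 2 and -0.98 in plate 4, so the direction differed between the plates. TOP2A, the topoisomerase of dividing cells, had a log2 fold of -0.67 (-0.85 in plate 2 and -0.28 in plate 4). Genes of S phase showed no comparable shift in the summed counts. The median of the 41 members was 0.11 (-0.07 to 0.30), at percentile 95.2, with 25 members higher and 16 lower. Fewer of them were read per PKH26 high cell at equal depth, with a median of 11 against 17 in PKH26 low cells. Within plates these medians were 11 and 21.5 in plate 2, and 10 and 14 in plate 4. DTL, an adaptor of the ubiquitin ligase that clears replication licensing factors (log2 fold 1.19), and POLA1, the catalytic subunit of DNA polymerase alpha (1.20), were higher in PKH26 high cells. EXO1, an exonuclease of mismatch repair, had a log2 fold of 1.47 that came mainly from plate 2 (2.45, against 0.14 in plate 4). CDCA7 had a log2 fold of -1.40 (-2.20 in plate 2 and -0.12 in plate 4).

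Genes that restrain the cell cycle or mark quiescence were mostly higher in PKH26 high cells. The median of the 17 members was 0.43 (0.20 to 0.94), at percentile 99.5, with 14 members higher, 10 of them in both plates. FOXO1, a transcription factor held back by AKT signalling, stood at 20.1 CPM in PKH26 high and 3.20 CPM in PKH26 low cells (log2 fold 2.33) and was read in 12 of 45 and 3 of 43 cells. CCNG2, an unusual cyclin induced at growth arrest, had a log2 fold of 1.06, and the antiproliferative gene TOB1 one of 0.94 (1.51 in plate 2 and 0.10 in plate 4). CDKN1B, which encodes the CDK inhibitor p27 (ENSG00000111276.6, chromosome 12, 12838432 to 12875303), stood at 14.8 CPM (13.9 to 15.8) and 6.85 CPM (6.21 to 7.54), with log2 folds of 1.66 in plate 2 and 0.22 in plate 4. CDKN1A, which encodes p21, stood at 213 CPM (209 to 216) in PKH26 high and with an interval of 169 to 175 CPM in PKH26 low cells, but its log2 fold was 1.40 in plate 2 and -1.04 in plate 4. GADD45B, a stress-induced gene of the same list, was lower in PKH26 high cells, at 12.8 against 48.4 CPM (log2 fold -1.84). The list median was 0.84 in plate 2 and 0.26 in plate 4, the latter inside the central 95% of random lists.

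Hypoxia response genes were higher in PKH26 high cells, with a median of 0.43 (0.08 to 0.76) over 21 members, 18 of them higher. PFKFB3, a kinase that raises the glycolytic activator fructose 2,6-bisphosphate (ENSG00000170525.14, chromosome 10, 6186897 to 6296607), stood at 22.4 CPM (21.3 to 23.6) in PKH26 high and 1.87 CPM (1.54 to 2.24) in PKH26 low cells, a log2 fold of 3.03. KDM3A, a histone demethylase induced by hypoxia, had a log2 fold of 1.64 (2.54 without the deepest cell of each group), ADM, the gene of adrenomedullin, one of 1.42, and the MYC antagonist MXI1 one of 1.07 that came from plate 4 (2.46, against 0.03 in plate 2). The hypoxia median was 0.03 in plate 2, inside the central 95% of random lists, and 0.72 in plate 4. All 13 mitochondrially encoded genes of their list were higher, with a median of 0.33 (0.18 to 0.70), led by the complex I subunits MT-ND6 (0.94), MT-ND3 (0.83) and MT-ND5 (0.70), and 12 of them were higher in both plates. The list median was 0.25 in plate 2, inside the central 95% of random lists, and 0.40 in plate 4. Beside this, mitochondrial reads made up a median of 6.98% of a PKH26 high cell's reads and 5.46% of a PKH26 low cell's, and 2 PKH26 high cells exceeded 15%. Without these cells the list median was 0.21, with 10 of 13 members higher. Nuclear genes of oxidative phosphorylation had a median of -0.01 (-0.08 to 0.10) and glycolysis genes one of 0.04 (-0.24 to 0.17).

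Genes of cholesterol synthesis and of ribosome assembly were lower in PKH26 high cells. The cholesterol list had a median of -0.34 (-0.62 to -0.19), at percentile 0.86, with 17 of 23 members lower. It was -0.56 in plate 2 and -0.32 in plate 4, the latter inside the central 95%. SQLE, the squalene epoxidase, had a log2 fold of -1.05 and MVD, a decarboxylase of the mevalonate pathway, one of -1.04. LSS, the lanosterol synthase, went the other way (0.85). The list of MYC targets and ribosome assembly had a median of -0.43 (-0.66 to -0.23), at percentile 0.06, with 19 of 22 members lower, 14 of them in both plates. It was -0.34 in plate 2 and -0.37 in plate 4, again the latter inside the central 95%. WDR43, a factor of early ribosome assembly, had a log2 fold of -1.02, with -0.11 in plate 2 and -2.85 in plate 4. NOP2, a methyltransferase of ribosomal RNA (-0.89), CAD, the enzyme that starts pyrimidine synthesis (-0.85), and MYBBP1A, a nucleolar protein (-0.79), were also lower, although NOP2 was at 0.06 and MYBBP1A at -0.17 in plate 4. Ribosomal protein genes had a median of 0.10 (0.02 to 0.15), with 0.25 in plate 2 and -0.15 in plate 4, and lay inside the central 95% with plate 4 cells alone, with equal weight per cell and with thinned cells.

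Immediate early genes were mostly higher in PKH26 high cells, with a median of 0.53 (0.12 to 0.89) and 13 of 16 members higher. The list median was 0.31 in plate 2, inside the central 95% of random lists, and 0.48 in plate 4, outside it. FOS, a subunit of the AP-1 transcription factor (ENSG00000170345.5, chromosome 14, 75745529 to 75748933), stood at 346 CPM (342 to 351) in PKH26 high and 141 CPM (138 to 144.4) in PKH26 low cells, with a log2 fold of 1.24 in plate 2 and 1.29 in plate 4. FOSB (log2 fold 0.84) and MCL1, a survival gene of the BCL2 family (0.59), were higher, and FOSL1, another AP-1 subunit, was lower (-1.07). The NF-kB and cytokine list had a median of 1.38 (-0.43 to 3.13), with 11 of 14 members higher. With the 4 members that had no read in a group set against the floor of 3 reads, the median was 1.68. BIRC3, an inhibitor of apoptosis induced by NF-kB, stood at 47.6 CPM (45.9 to 49.3) in PKH26 high and 10.5 CPM (9.71 to 11.3) in PKH26 low cells, with log2 folds of 2.09 and 2.25 in plates 2 and 4. NFKBIZ, a nuclear regulator of NF-kB, had a log2 fold of 1.07. The neutrophil chemokine CXCL1 stood at 29.0 CPM in PKH26 high cells and had no read in PKH26 low cells. Against a floor of 3 reads over the group it was 596-fold higher, but 2 of 45 PKH26 high cells held its reads at equal depth. The list median was 1.89 in plate 2 and 0.56 in plate 4, the latter inside the central 95%. The nuclear RNAs MALAT1 and NEAT1 (log2 folds of 1.42 each) and the share of mitochondrial reads were higher in PKH26 high cells too. Without cells above 15% mitochondrial reads the quiescence, immediate early and NF-kB lists stayed outside the central 95%, but an effect of RNA quality below that limit on these lists was not tested.

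CD44, the hyaluronan receptor used as a surface marker of breast cancer stem cells (ENSG00000026508.12, chromosome 11, 35160429 to 35253949), stood at 539 CPM (533 to 544.5) in PKH26 high and 248 CPM (244 to 252) in PKH26 low cells, with log2 folds of 1.14 in plate 2 and 1.07 in plate 4. Its share of cells with a read differed little, with 43 of 45 and 39 of 43 cells. Among integrins and matrix genes, ITGB5 (log2 fold 1.23) and ITGAV (1.11), which encode the subunits of a vitronectin receptor, and the basement membrane collagen gene COL4A1 (1.16) were higher, and the laminin gene LAMB1 was lower (-1.14). The list median was 0.22 (-0.23 to 0.55), at percentile 99.6, with 14 of 26 members higher. With plate 2 cells alone it was 0.08, inside the central 95% of random lists, and with plate 4 cells 0.35, outside it. The mesenchymal list had a median of 0.31 (-0.37 to 0.55), at percentile 98.01, and 11 of 16 members were higher. VIM, the gene of vimentin (ENSG00000026025.9, chromosome 10, 17270240 to 17279592), stood at 4656 and 3629 CPM (log2 fold 0.36), and ZEB1, a repressor of epithelial genes, at 124 and 58.6 CPM (1.07). The receptor kinase gene AXL (-0.73) and the calcium-binding protein gene S100A4 (-0.66) were lower. TGFBI, which encodes a matrix protein induced by TGF-beta, had log2 folds of 2.00 in plate 2 and -0.33 in plate 4, and the list median was 0.15 in plate 2 and -0.35 in plate 4, inside the central 95% in both. It also fell inside with equal weight per cell, with thinned cells and with a pseudocount of 5 CPM.

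Stem cell associated genes had a median of 0.12 (-0.31 to 1.12), with 7 of 13 members higher. ALDH1A3, an aldehyde dehydrogenase, stood at 3.04 CPM (2.62 to 3.50) in PKH26 high cells, where 3 of 45 cells held its reads, and had no read in PKH26 low or G1 adherent cells. It was 62.4-fold higher than in PKH26 low cells against a floor of 3 reads over the group. PROM1, which encodes CD133, had no read in any group. The floor of 3 reads corresponds to 0.0482 CPM in PKH26 high, 0.0487 CPM in PKH26 low and 0.0719 CPM in G1 adherent cells. Epithelial genes had a median of 0.24 (-0.29 to 0.64), with 5 of 9 members higher, among them KRT18, the gene of a simple epithelial keratin (log2 fold 0.64).

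**Figure D2:**
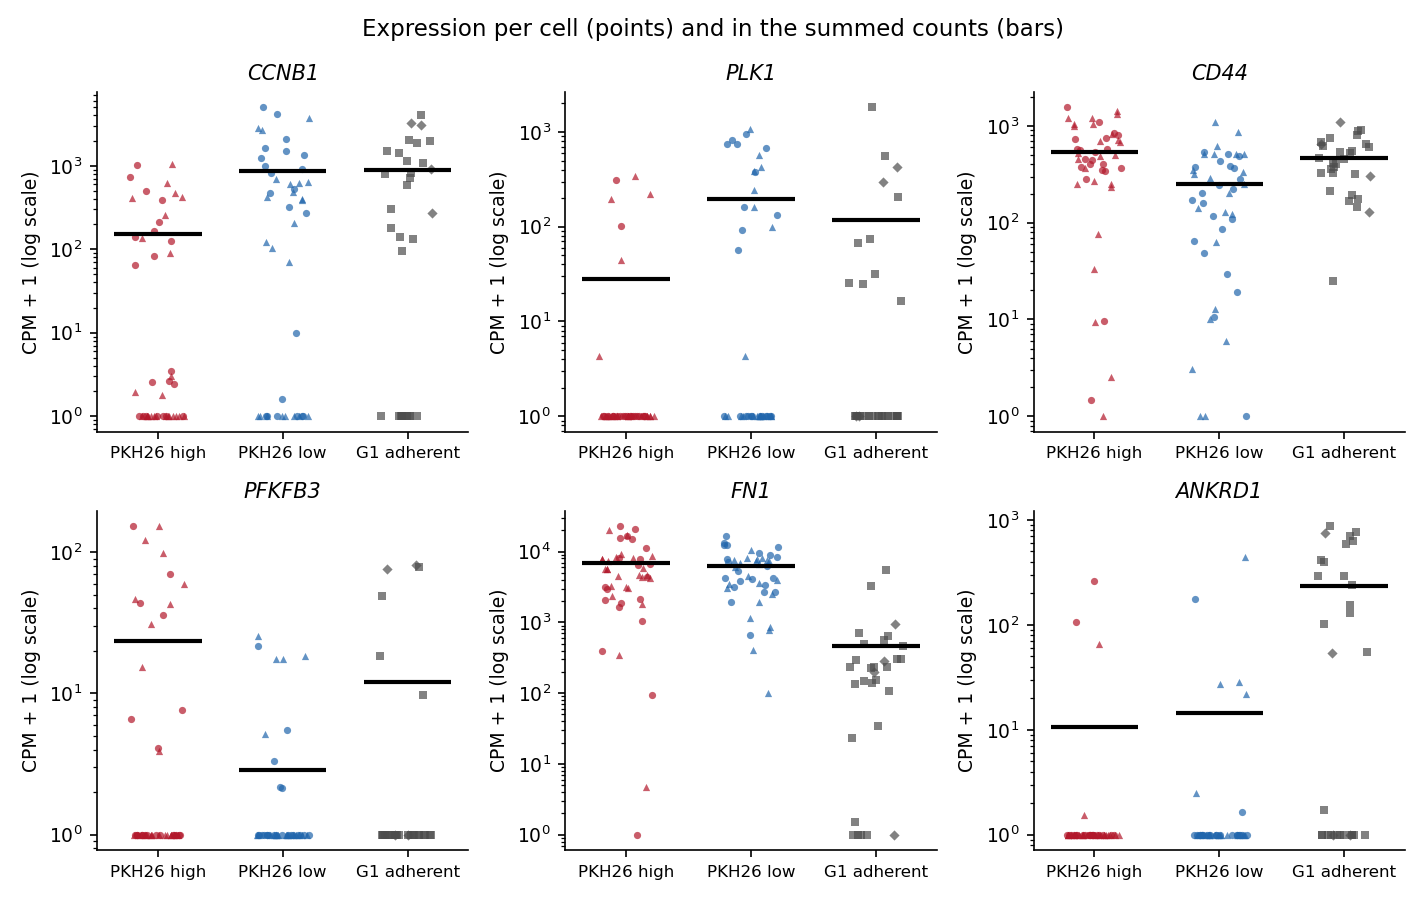
Level of CCNB1, PLK1, CD44, PFKFB3, FN1 and ANKRD1 in each cell as CPM + 1 on a log axis, with circles for plate 2, triangles for plate 4, squares for plate A and diamonds for plate B, and bars at the summed CPM + 1 of each group. The summed level of CD44 is 539 CPM in PKH26 high and 248 CPM in PKH26 low cells, and that of FN1 is 6965, 6196 and 469 CPM in PKH26 high, PKH26 low and G1 adherent cells.

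Single genes were named by a rule of size, which took the 12 with the highest and the 12 with the lowest fold among genes that differed at least 2-fold in the sums, in each plate and with equal weight per cell. Higher in PKH26 high cells were CALCOCO1, an autophagy receptor (ENSG00000012822.11, chromosome 12, 54102301 to 54121529; log2 fold 4.23, at 37.9 CPM, 36.4 to 39.5, against 1.07 CPM, 0.829 to 1.36), GTDC1 (3.16), SLFN5 (3.08), FAM8A1 (3.04), PFKFB3 (3.03), the vesicle coat gene SEC31B (2.96), the nuclear receptor gene PPARD (2.91), the stress-responsive kinase gene PLK3 (2.82), TGFA, a ligand of the EGF receptor (2.72), AP5S1 (2.67), the natriuretic peptide receptor gene NPR2 (2.65) and TEX2 (2.61). Lower were NOX5, a calcium-activated NADPH oxidase gene (ENSG00000255346.5, chromosome 15, 69307034 to 69355102; log2 fold -4.52, at 0.563 CPM, 0.392 to 0.783, against 34.8 CPM, 33.4 to 36.3), TRABD2A (-3.98), GAS2L3 (-3.81), BANP (-3.49), PDCD2L (-3.35), OSBPL11 (-3.32, and -4.06 without the deepest cell of each group), RBM45 (-3.20), PRTFDC1 (-3.18), NOP14 (-3.06), PUSL1 (-2.92), NOL9 (-2.90) and PLK1 (-2.78). NOP14 and NOL9 act in ribosome assembly. CALCOCO1 was read in 15 of 45 PKH26 high and 4 of 43 PKH26 low cells, and NOX5 in 2 and 11 cells. Among simulated genes with no difference, drawn from the same cells' spread, the largest absolute log2 folds that met the same rule were 3.40 on the higher and 3.54 on the lower side. Only CALCOCO1, NOX5, TRABD2A and GAS2L3 of the 24 named genes exceeded those values. The simulation held no difference between plates. Its unchanged genes had within-plate log2 folds with SDs of 1.02 in plate 2 and 0.995 in plate 4, against 1.25 and 1.34 over all 10883 measured genes. The gene sets differ, since measured genes needed 5 CPM in any of the 3 groups and simulated ones 5 CPM over the PKH26 cells together. How much of the gap in SD comes from this was not tested. The largest simulated folds may be too low, and exceeding them does not exclude chance.

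Of the 26 lists with a median, 13 lay outside the central 95% of random lists in PKH26 high against PKH26 low cells. Besides those above, they were ERK feedback and EGF receptor genes (0.18, percentile 97.7, with -0.17 in plate 2 and 0.20 in plate 4), with EGFR and its ligand gene HBEGF both lower (-1.07 each), and lysosome and autophagy genes (0.16, percentile 98.2). The ERK list fell inside the central 95% in each plate, with equal weight per cell, with thinned cells and under further alternatives, and the lysosome list in plate 2 cells, with thinned cells and with no gene filter. The list medians inside the central 95% and not given above were -0.08 for basal keratins, -0.24 for fatty acid synthesis, -0.29 for heat shock, 0.03 for the unfolded protein response, -0.08 for p53 targets, -0.20 for the interferon response and -0.20 for YAP/TAZ targets, and NRF2 targets stood at 0.998-fold. The random lists do not carry the shared variation of list members from cell to cell. As a yardstick for it, the absolute list median between plates 2 and 4 within a group had a median of 0.189 and a 90th percentile of 0.462 over 52 values. Among the 13 lists, those of G2/M, NF-kB, immediate early, cholesterol, MYC target, mesenchymal and integrin genes had a larger absolute median than the same list showed between the plates of either group, while those of quiescence, hypoxia, mitochondrially encoded, ribosomal protein, ERK and lysosome genes did not. Of the lists with a larger median, only those of G2/M, cholesterol and MYC target genes also exceeded it, with the same sign, in plate 2 alone and in plate 4 alone. For the NF-kB list, PKH26 high cells of plates 2 and 4 themselves differed by 1.04.

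**Figure D3:**
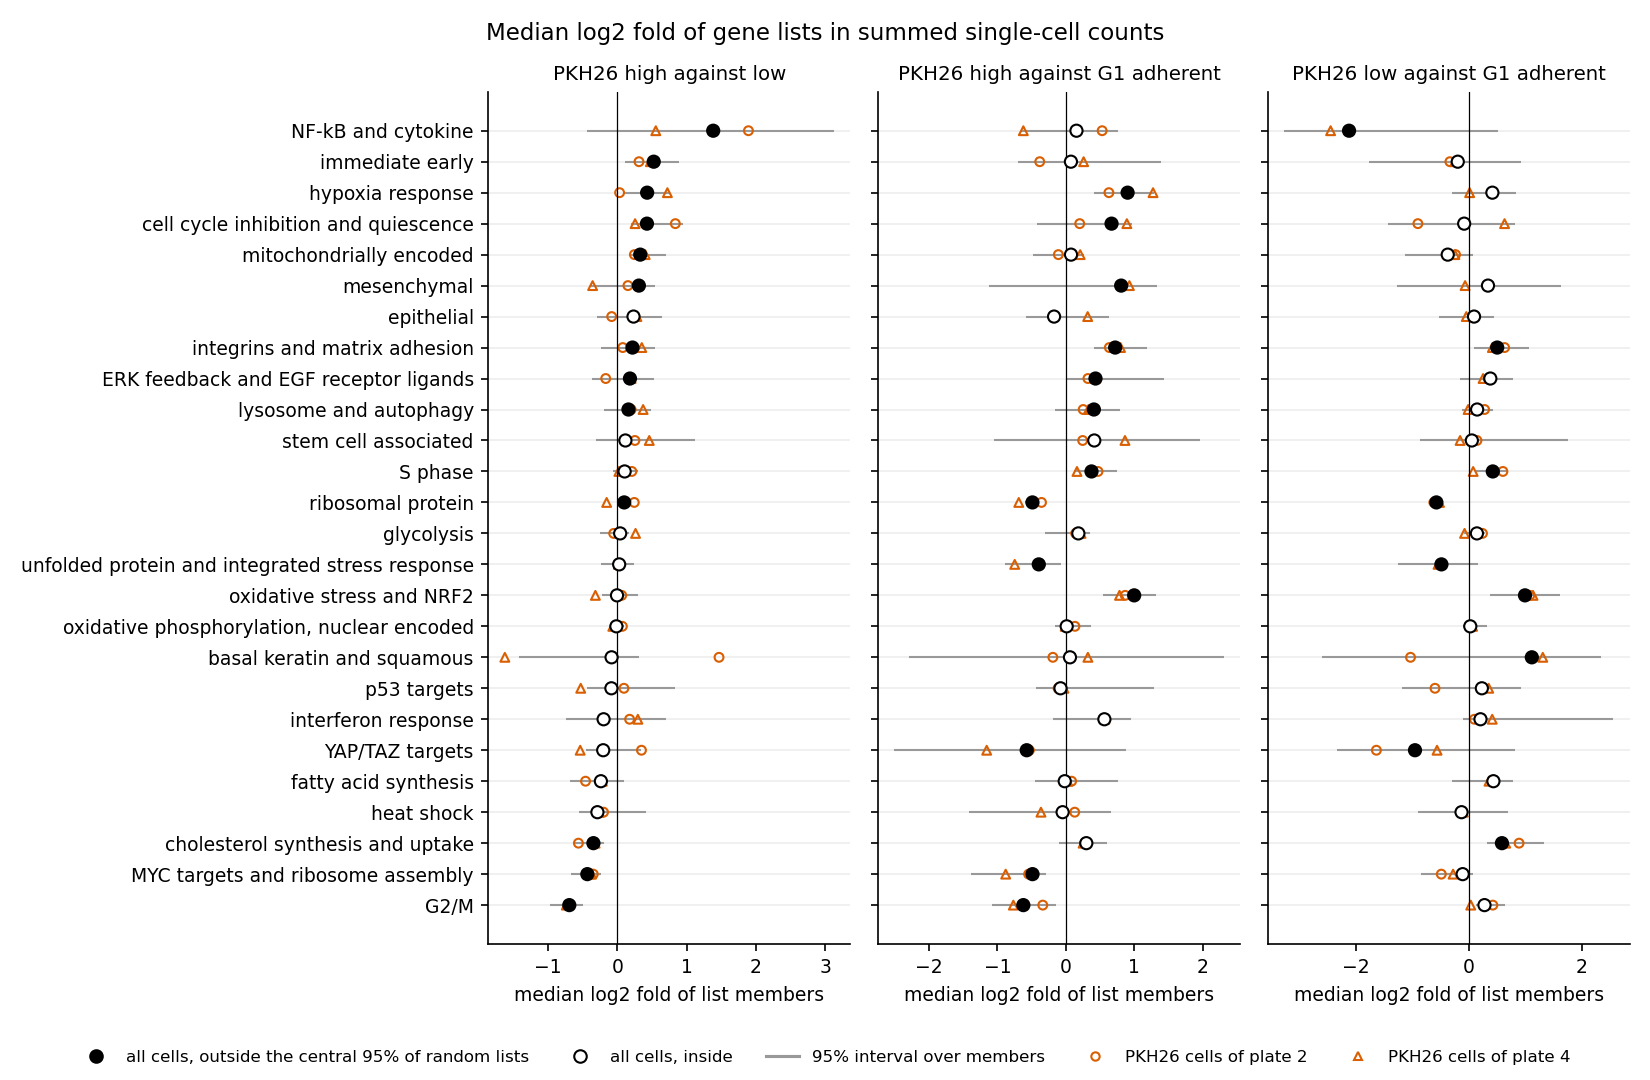
Median log2 fold of each gene list on the horizontal axis for PKH26 high against low, PKH26 high against G1 adherent and PKH26 low against G1 adherent cells, with bars for the 95% interval over list members, filled circles for lists outside the central 95% of random lists, and orange circles and triangles for PKH26 cells of plates 2 and 4 alone. The G2/M median is -0.69 in PKH26 high against low cells, -0.62 in PKH26 high against G1 adherent cells and 0.27 in PKH26 low against G1 adherent cells.

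The comparison of mammosphere with adherent cells asks how the PKH26 groups differ from cells of the same line in adherent culture. Matrix and adhesion genes were higher in both PKH26 groups. FN1, the gene of fibronectin (ENSG00000115414.14, chromosome 2, 216225163 to 216300796), stood at 6965 CPM (6944 to 6986) in PKH26 high, 6196 CPM (6176 to 6216) in PKH26 low and 469 CPM (463 to 476) in G1 adherent cells. COL6A1, a collagen VI gene, had log2 folds of 3.67 in PKH26 high and 3.02 in PKH26 low cells against G1 adherent cells, the laminin gene LAMC1 ones of 2.14 and 1.51, and THBS1, the gene of thrombospondin 1, ones of 1.41 and 1.70. The integrin and matrix list had medians of 0.72 (0.42 to 1.19) and 0.50 (0.09 to 1.05), with 22 and 21 of 26 members higher. For PKH26 low cells the list fell inside the central 95% of random lists with equal weight per cell, with thinned cells, with a pseudocount of 5 CPM and with plate 4 cells alone. The medians of all genes were 0.10 and 0.14. Culture, staining, sorting gate, plate and date cannot be told apart in any difference from G1 adherent cells, and both comparisons share the same 30 G1 cells.

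NRF2 and oxidative stress genes were higher in both PKH26 groups than in G1 adherent cells, with medians of 1.00 (0.54 to 1.32) and 0.99 (0.37 to 1.61) and 15 and 16 of 17 members higher. NQO1, a quinone reductase gene (ENSG00000181019.8, chromosome 16, 69740899 to 69760571), stood at 2183 CPM (2171 to 2194) in PKH26 high, 2187 CPM (2175 to 2198) in PKH26 low and 406 CPM (400.2 to 412) in G1 adherent cells. FTH1, the gene of ferritin heavy chain, had log2 folds of 1.74 and 1.25, and the metallothionein genes MT1X (1.32 and 0.99) and MT2A (1.19 and 1.19) were higher as well. GCLM, a subunit of the enzyme that starts glutathione synthesis, had log2 folds of 1.00 and 1.72, and the cystine transporter gene SLC7A11 ones of 1.04 and 1.61. Cholesterol genes had medians of 0.30 (-0.10 to 0.60) in PKH26 high and 0.58 (0.31 to 1.32) in PKH26 low cells, with 16 and 21 of 23 members higher. HMGCS1 (2.77 and 3.07) encodes an enzyme at the start of the mevalonate pathway, and TM7SF2 (1.92 and 1.77) and ACAT2 (0.66 and 1.40) other steps of sterol synthesis.

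YAP/TAZ target genes were split, with some members lower and others higher in the PKH26 groups. CCN2 (log2 folds -2.94 and -2.76) and CCN1 (-2.61 and -2.34) encode secreted matricellular proteins. ANKRD1, another YAP target (ENSG00000148677.6, chromosome 10, 92671853 to 92680844), stood at 9.57 CPM (8.81 to 10.4) in PKH26 high, 13.4 CPM (12.5 to 14.3) in PKH26 low and 235 CPM (230.2 to 239) in G1 adherent cells. IGFBP3, which binds insulin-like growth factors (3.72 and 2.60), and AMOTL1, a binding partner of YAP (1.96 and 2.36), were higher. The list medians were -0.57 (-2.50 to 0.88) and -0.96 (-2.34 to 0.81), at percentiles 0.18 and 0, with 13 of 22 members lower in each. The growth regulator MYC (ENSG00000136997.10, chromosome 8, 128747680 to 128755197) stood at 126 CPM (124 to 129), 148 CPM (144.5 to 151) and 837 CPM (828 to 845), and the phosphatase gene DUSP1, induced by growth factors and stress, had log2 folds of -2.60 and -2.78. EGR1, another immediate early gene, was higher (2.01 and 1.61), and so was SPRY1, a feedback inhibitor of receptor kinases (2.59 and 2.13). The MYC target and ribosome assembly list had medians of -0.49 in PKH26 high and -0.11 in PKH26 low cells.

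Ribosomal protein genes were lower in the PKH26 groups, in 49 of 50 members for PKH26 high cells (median -0.49, -0.60 to -0.41) and 48 of 50 for PKH26 low cells (-0.58, -0.65 to -0.48), among them RPSA (-1.06 and -1.07), RPLP0 (-0.95 and -0.85) and RPL12 (-0.85 and -1.09). They took a median of 4.82% of reads in a PKH26 high cell, 4.67% in a PKH26 low cell and 7.25% in a G1 adherent cell. The unfolded protein and integrated stress list had medians of -0.40 (-0.89 to -0.07) and -0.49 (-1.25 to 0.16), with 18 and 17 of 24 members lower. For PKH26 high cells it lay inside the central 95% of random lists with plate 2 cells alone (-0.38, percentile 2.58). Its lower members included TRIB3 (-2.15 and -1.97), ASNS, the asparagine synthetase gene (-2.10 and -1.50), CHAC1, a glutathione-degrading enzyme (-2.34 and -1.16), and DDIT3, a stress-induced transcription factor, at 74.01 CPM in PKH26 high, 32.5 in PKH26 low and 148.6 in G1 adherent cells. VLDLR, a lipoprotein receptor gene of this list, was higher (2.55 and 2.51). Among heat shock genes, the chaperone gene HSP90AB1 was lower (-1.34 and -0.90) and the co-chaperone gene BAG3 higher (2.02 and 1.43). Hypoxia response genes had medians of 0.90 (0.41 to 1.28) in PKH26 high and 0.41 (-0.30 to 0.83) in PKH26 low cells. NDRG1 (1.83 and 0.83), the oxygen sensor gene EGLN3 (1.94 and 1.54), the adenylate kinase gene AK4 (1.38 and 0.67) and VEGFA, which encodes an angiogenic growth factor (1.23 and 1.60), were higher, while ADM (-1.002 and -2.42) and DDIT4, an inhibitor of mTORC1 signalling (-0.89 and -1.53), were lower. PFKFB3 was higher in PKH26 high (0.95) and lower in PKH26 low cells (-2.08).

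The G2/M list was lower in PKH26 high than in G1 adherent cells, and PKH26 low cells were not set apart from G1 adherent cells by it. In PKH26 high cells its median was -0.62 (-1.08 to -0.15), at percentile 0, with 35 of 52 members lower, and in PKH26 low cells it was 0.27 (0.12 to 0.64), at percentile 94.2, with 34 of 52 members higher. CCNB1 stood at 900 CPM (890.5 to 909) in G1 adherent cells, close to PKH26 low cells (log2 fold -0.07), and reads of it were found in 21 of 30 G1 adherent cells. At equal depth a G1 adherent cell held reads of a median of 24.5 genes of the list (range 10 to 50), no fewer than the 22 of PKH26 low cells. G2/M transcripts do not set the cells sorted as G1 apart from PKH26 low cells. The G2/M and S phase differences from this group should therefore not be read as differences from G1 cells alone. S phase genes did differ in number read per cell at equal depth, with medians of 11.5 in G1 adherent, 17 in PKH26 low and 11 in PKH26 high cells. Whether the gate let other cells through was not tested. CDC20 had log2 folds of -2.29 in PKH26 high and -0.46 in PKH26 low cells, DLGAP5, a spindle protein gene, ones of -2.31 and -1.61, and the checkpoint kinase gene BUB1 ones of -2.05 and -0.48. MKI67 (1.40 and 1.51), TOP2A (1.03 and 1.70) and the helicase gene BLM (3.36 and 3.10) were higher in both PKH26 groups than in G1 adherent cells. S phase genes had medians of 0.37 (0.12 to 0.75) and 0.42 (0.10 to 0.68). Both fell inside the central 95% of random lists with plate 4 cells alone (0.16 for PKH26 high cells), with the stricter gene filter and with a pseudocount of 5 CPM. In PKH26 low against G1 adherent cells, the medians of plate 4 cells alone were 0.03 for G2/M and 0.07 for S phase genes, and the G2/M median was 0.44 without the deepest cell of each group. In that comparison 26 of the 52 G2/M members were higher with each plate alone. Between the plates of PKH26 low cells, the G2/M list differed by 0.40, plate 2 over plate 4.

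Some genes of the NF-kB list were lower in PKH26 low than in both other groups. The list median of PKH26 low against G1 adherent cells was -2.13 (-3.28 to 0.52), with 11 of 14 members lower and 4 without a read in a group, and that of PKH26 high against G1 adherent cells was 0.16 (-0.66 to 0.77). The former depended on the gene filter, since with the stricter one 7 members remained, with a median of -0.30 inside the central 95% of random lists. CXCL8, the gene of interleukin-8, stood at 9.57 CPM (8.81 to 10.4) in PKH26 high, 0.211 CPM (0.112 to 0.361) in PKH26 low and 8.75 CPM (7.87 to 9.69) in G1 adherent cells, and at equal depth 8 of 45, 1 of 43 and 2 of 30 cells held its reads. BIRC3 had log2 folds of 0.17 (0.59 in plate 2 and -0.62 in plate 4) and -1.91 against G1 adherent cells, and the chemokine gene CXCL2 ones of -0.66 and -3.76. CD44 stood at 467 CPM (461 to 474) in G1 adherent cells, with log2 folds of 0.20 in PKH26 high and -0.91 in PKH26 low cells. S100A4 (2.64 and 3.30) and VIM (0.71 and 0.36) were higher in both PKH26 groups than in G1 adherent cells, and GADD45B (-3.72 and -1.88) and AXL, at 739, 1229 and 2453 CPM, were lower. The mesenchymal list had medians of 0.81 (-1.13 to 1.33) and 0.33 (-1.29 to 1.62), with 11 and 10 of 16 members higher. The quiescence list, which holds GADD45B, had medians of 0.67 (-0.42 to 0.96) and -0.09 (-1.43 to 0.81), with 11 and 8 of 17 members higher. For PKH26 high cells both lists lay outside the central 95% of random lists. The quiescence list fell inside it with equal weight per cell and with thinned cells.

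The rule of size for mammosphere against adherent cells asked for the same direction in both PKH26 groups. KYNU, a hydrolase of tryptophan breakdown (ENSG00000115919.10, chromosome 2, 143635226 to 143813402), stood at 100.1 CPM (97.6 to 103) in PKH26 high and 113 CPM (110.7 to 116) in PKH26 low cells and had no read in G1 adherent cells. Against a floor of 3 reads over the group it was 1393-fold and 1576-fold higher, MARVELD1 342-fold and 420.3-fold, and the kinase gene CAMK1D 592-fold and 321-fold. PHF12, with 3 reads in G1 adherent cells, stood at 29.3, 24.4 and 0.0719 CPM (0.0148 to 0.210). The other genes higher in the PKH26 groups were TBXAS1, the thromboxane synthase gene (log2 folds 5.27 and 5.35), TATDN2 (4.46 and 4.53), the sphingosine phosphate receptor gene S1PR3 (4.03 and 3.98, the latter 3.26 without the deepest cell of each group), EPHX1, an epoxide hydrolase gene (3.91 and 3.92), the sorting receptor gene SORL1 (4.30 and 3.79), FN1 (3.89 and 3.72), CHMP6 (3.67 and 4.67) and the interleukin-4 receptor gene IL4R (3.74 and 3.61).

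Lower in both PKH26 groups were ADAMTS6, a secreted metalloprotease gene (ENSG00000049192.10, chromosome 5, 64444565 to 64777747), at 0.289 CPM (0.171 to 0.457) in PKH26 high, 2.19 CPM (1.84 to 2.60) in PKH26 low and 209 CPM (205 to 214) in G1 adherent cells, PAEP (log2 folds -4.42 and -4.14), ANKRD1 (-4.48 and -4.04), AOX1, the aldehyde oxidase gene (-4.70 and -3.25), the kinase genes PRKCH (-3.45 and -3.57) and SGK1 (-3.60 and -3.32), PRCD (-3.23 and -4.31) and ADTRP (-3.00 and -3.13). HSPB8, a small heat shock protein gene, stood at 0.0965 CPM in PKH26 high, had no read in PKH26 low (569-fold lower against the floor) and stood at 27.7 CPM in G1 adherent cells. RIMS2 had no read in PKH26 high cells (792-fold lower against the floor), 1.33 CPM in PKH26 low and 38.2 CPM in G1 adherent cells. MPP4, with 1 read in PKH26 high cells, stood at 0.0161 CPM (0.000407 to 0.0896), 2.92 CPM and 68.1 CPM, and ARRDC4, with 3 reads in PKH26 low cells, at 2.78, 0.0487 and 49.1 CPM. In simulated genes with no difference, the largest absolute log2 folds that met this rule were 3.17 on the higher and 2.82 on the lower side, and each of the 24 named genes exceeded them. The simulation held no difference between plates, dates or cultures, so it bears on the sampling of cells alone. ADAMTS6 was read in 15 of 30 G1 adherent cells at equal depth.

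The 2 leading principal components of the cells, over the 1000 most variable genes, carried 8.72% and 3.72% of the variance. The leading component was headed by BIRC5, PTTG1, TYMS, NUSAP1, PRC1 and TOP2A, genes used in mitosis or in DNA synthesis. Its Spearman correlation across cells was 0.886 with the number of G2/M list genes read and 0.698 with the number of all genes read, both at equal depth, and these were not separated. G2/M list genes such as TOP2A, CDC20, DLGAP5 and CCNB1 are among its leading genes, so the former correlation is partly built in. The median of the leading component was -18.5 in PKH26 high, 9.93 in PKH26 low and 20.1 in G1 adherent cells. The next component had FN1, GSN and S100A4 on its positive side and MYC, CCN1 and DUSP1 on its negative side, with medians of 10.6, 10.4 and -31.6. These leading genes were read off the components after their values were seen. On the leading component the medians of plates 2 and 4 were -4.16 and -25.0 in PKH26 high and 14.4 and -15.2 in PKH26 low cells.

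**Figure D4:**
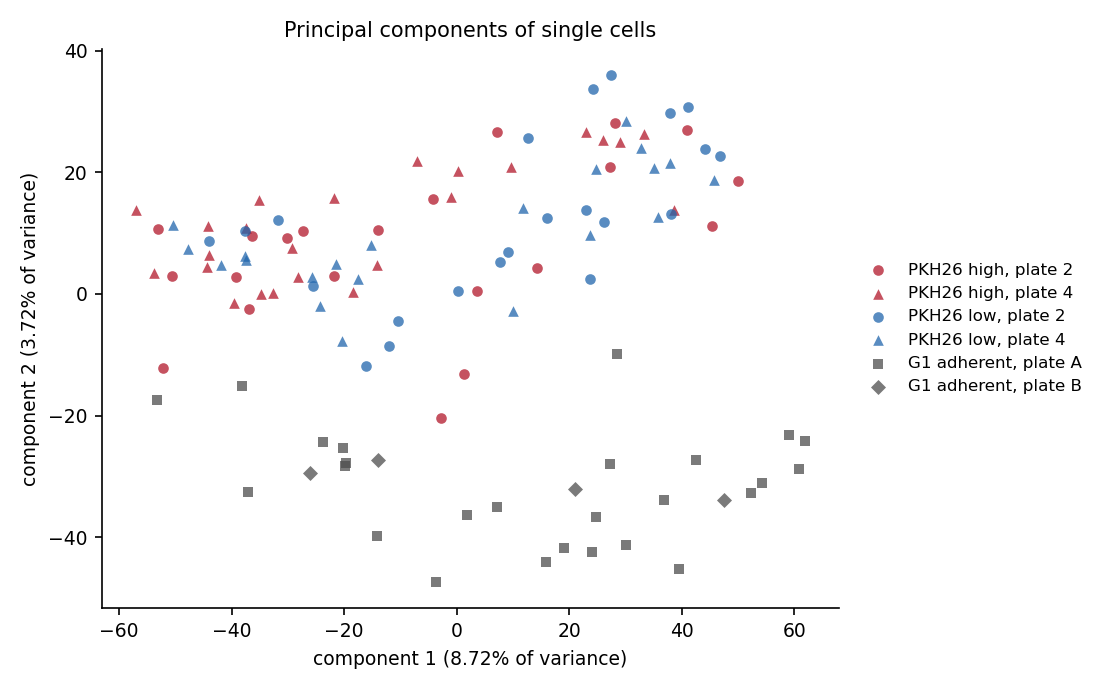
Position of each cell on the leading component (horizontal axis, 8.72% of the variance) and the next component (vertical axis, 3.72%), in arbitrary units, with 1 point per cell thinned to 500000 reads, colours for the 3 groups and mark shapes for the plates. G1 adherent cells lie lower on the vertical axis, with a median of -31.6 against 10.6 and 10.4, and the groups overlap on the horizontal axis.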

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

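Leaving out cells above 15% mitochondrial reads was chosen after the results were seen, and the other alternatives before. Over all alternatives, 1200 list medians stayed within the interval over members of the reported value, 15 moved outside it, and 4 of lists outside the central 95% changed sign. Medians close to 0 inside the central 95% also crossed 0. The basal keratin list had too few members for a value under the stricter gene filter. The sign changes were in the mesenchymal list (-0.35), the ribosomal protein list (-0.15) and, among the reported gene folds of at least 2-fold, that of TGFBI (-0.33), all in plate 4 cells of PKH26 high against low, in the ERK feedback list of the same comparison in plate 2 cells (-0.17), and in the basal keratin list of PKH26 low against G1 adherent cells in plate 2 cells (-1.04). With plate 4 cells alone, the medians of PKH26 low against G1 adherent cells were 0.0284 for G2/M and 0.0715 for S phase genes. The cause was not tested, and fewer cells entered each of these values. For PKH26 high against low, the G2/M median lay between -0.73 and -0.64 over all alternatives, at percentile 0 in each, and the S phase median between -0.04 and 0.21. For PKH26 high against G1 adherent cells these ranges were -0.77 to -0.34 and 0.16 to 0.63.

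Of the 13 lists outside the central 95% in PKH26 high against low, 12 kept their sign in plate 2 and 11 in plate 4, and 6 stayed outside the central 95% in plate 2 cells and 6 in plate 4 cells, but only the G2/M list did so in both, and the other 12 lost that place in 1 plate or both. Of the gene folds reported in the text, over all alternatives, 2799 values stayed within their counting interval and 1227 moved outside it, which is narrow for well-read genes, and 1 fold of at least 2-fold changed sign. Folds of the named genes in comparisons where the text reports none are not counted, and some of them changed sign in a single plate. All 36 shares of cells stayed within their intervals and the 6 numbers of genes per cell within the spread of cells without thinning and at 200000 reads. All cells passed the filter, so dropping it changed nothing, and the other scalings moved the median of all genes by -0.0887 at the most, on the log2 scale. Depth limits low genes, since 3 reads correspond to 0.0482, 0.0487 and 0.0719 CPM in PKH26 high, PKH26 low and G1 adherent cells. No paired analysis was possible because the result comes from no test and the cell numbers that the groups share in their titles only name cells, while the plates that PKH26 high and low cells share were used for folds within each plate.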

Other observations

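The 5 tests on GCG and MALAT1 were chosen after the results were seen, and the 2 tests on the plates before. Genes of the lysosome and autophagy list went both ways between PKH26 high and low cells. NPC1, a lysosomal cholesterol exporter, had a log2 fold of 1.16 (1.22 in plate 2 and 1.13 in plate 4), while MCOLN1, a lysosomal calcium channel (-1.17), and GABARAPL1, a protein of the autophagosome membrane (-1.22, and -0.63 without the deepest cell of each group), were lower in both plates. Among p53 targets, MDM2, the ligase that degrades p53, stood at 15.5 CPM in PKH26 high and 41.4 CPM in PKH26 low cells (log2 fold -1.36, with -1.62 and -1.19 in plates 2 and 4). TP53I3, another gene of that list, was higher in both PKH26 groups than in G1 adherent cells (2.31 and 2.61). The mitochondrial chaperone genes HSPD1 (-0.66) and HSPE1 (-0.55) were lower in PKH26 high than in PKH26 low cells in both plates. The hair keratin gene KRT81 was lower in both PKH26 groups than in G1 adherent cells (-2.29 and -2.61). Its basal keratin list had medians of 0.06 (-2.29 to 2.30) and 1.11 (-2.61 to 2.33) there, with 3 of 5 members higher in each. LOX, a collagen cross-linking enzyme of the hypoxia list, had log2 folds of 1.28 and 0.85 against G1 adherent cells, with -1.35 for PKH26 low cells of plate 4 alone.

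Markers of cell types that the line should lack were low in summed CPM, but CD68 was not absent. Leukocyte markers summed to 3.01 CPM in PKH26 high, 3.67 in PKH26 low and 8.51 in G1 adherent cells. CD68 alone took 7.21 CPM in G1 adherent cells and was read in 76.7% of them, and in 27.9% of PKH26 low cells. Endothelial markers summed to 1.08, 0.0325 and 0.575 CPM, and erythroid markers had no read.

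GCG, the gene of glucagon (ENSG00000115263.10, chromosome 2, 162999392 to 163008914), had reads in every cell of the 3 groups, at 2530 CPM in PKH26 high, 2775 CPM in PKH26 low and 4664 CPM in G1 adherent cells. RNA of other endocrine cells is argued against, since INS, SST, TTR, IAPP, CHGA and PPY together reached at most 0.00127% of the GCG reads. A fixed amount of template in every well may be the source, because GCG varied less per spike-in read than per gene read, with a ratio of the SDs of log2 values of at most 0.841. Transcription by the line stays open, although GCG had the lowest such ratio among the genes above 500 CPM in each group (percentile 0), since a transcript kept at a constant number per cell gives the same values. GCG reads per spike-in read had medians of 1.48, 1.60 and 5.35. Values per spike-in read assume an equal amount of spike-in RNA in each well, which is not known.

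MALAT1, a long non-coding RNA retained in the nucleus (ENSG00000251562.3, chromosome 11, 65265111 to 65275544), stood at 7572 CPM in PKH26 high, 2835 CPM in PKH26 low and 2862 CPM in G1 adherent cells, a log2 fold of 1.42 between the PKH26 groups, and NEAT1, another nuclear RNA, had one of 1.42 and the mitochondrial ribosomal RNA MT-RNR2 one of 0.84. A few damaged cells are argued against, since without cells above 15% mitochondrial reads the MALAT1 fold was 1.37 in plate 2 and 1.32 in plate 4. Less of all other RNA per cell is argued against as well, if the wells of a plate held equal amounts of spike-in RNA. MALAT1 reads per spike-in read were higher in PKH26 high cells, with ratios of the medians of 2.96 in plate 2 and 2.12 in plate 4. As a hypothesis, MALAT1 may be more abundant in cells that divided less, although damage below that mitochondrial limit was not tested.

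Gene folds of PKH26 high against low repeated poorly between plates, with a correlation of 0.0827 across the 10883 genes, which are not independent replicates. Simulated unchanged genes, from a gene set chosen by another limit, had one of 0.004. Few cells with reads of a gene could account for the poor repeat. The correlation was higher by 0.159 for genes read in at least 75% of cells than for those read in under 25%. That difference lay between the bounds set in advance, so it decides nothing. A difference between plates that acts on the groups unequally stays open too, since the genes read in at least 75% of cells reached a correlation of 0.232, above the limit set for that explanation and below the one that would exclude it. These explanations cannot be told apart with 2 plates.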
